A study of Mus musculus with 8 samples.

How the data were processed

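Total RNA of mouse cells was profiled on 8 one-colour Illumina bead arrays, 1 per sample. Per the labels, 3 samples were mouse embryonic stem cell lines (mESC), 3 were XEN cells converted from such cells (cXEN) and 2 were XEN cell lines derived from embryos (eXEN). The labels name the mESC as the negative control and the eXEN as the positive control. RNA was taken with Trizol, treated with DNase and turned into biotin-labelled cRNA. XEN cells were kept in XEN medium. The labels give the mESC medium in conflicting ways: the protocol names serum and LIF for 2 days before RNA was taken, while the sample names carry KSR and LIF. Which medium was used is not settled here, so each comparison with mESC also compares culture media.

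The deposited raw table gives the intensity of each probe, averaged over its beads on a linear scale. From the values, which are all above 0, no background had been subtracted. Per the file headers it also holds a detection p-value per probe and array, as deposited by the authors. The deposited normalized table gives log2 values, although dim signals are compressed, as by a variance-stabilizing transform. Their normalization is not stated in the sources used here. The sorted values of all 8 columns are equal within a tolerance of 0.001, with a largest difference of 0.000769, as in a quantile normalization. That tolerance was set after the largest difference had been seen. At the tolerance tried first, 1e-06, 1 column counted as equal, and that is the column the others are compared with. The values of the series matrix were the same as those of the normalized values, with a largest difference of 0. The lowest rank correlation of an array's raw and normalized values was 1.

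Values were computed from the raw intensity with the neqc function of limma 3.58.1 in R 4.3.3, with the data.table package (version 1.17.8). The background mean and SD of each array were taken from the detection p-values. An offset of 16 was added, the arrays were quantile normalized and values were put on the log2 scale. A probe was tested when its detection p was below 0.01 on at least 2 arrays, which left 17654 of 45281 probes and 12603 genes. Probes were named through gene identifiers (29586 probes), through accessions (2759) or by the symbol in the file alone (12936). Of the tested probes, 2947 had the file symbol alone, which can be an old name. Each gene was read by its probe with the highest mean. Of the 3621 genes with several tested probes, 11 had probes called in opposite directions in cXEN minus mESC, 15 in eXEN minus mESC and 0 in cXEN minus eXEN. The files name no genome build for the probe positions. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6. A further 24 per-sample columns of the deposited tables were not used here.

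The background mean was 85.4 on cXEN3, 86.9 on eXEN2 and between 62.0 and 68.2 on the other arrays. Between 13935 and 15408 probes were detected per array, or 30.8% to 34.0%. The number of arrays limits the precision of every value below.

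A linear model was fitted with limma to all 8 arrays, with moderated standard errors (SE). Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg over the probes of each comparison. A gene was called at an adjusted p below 0.05. The terms higher and lower refer to called genes. Where a probe had a detection p of 0.01 or more on every array of a group, its fold is given as a lower bound, with that group set to the lowest value among detected probes where its own value was below it. Log2 values of such probes enter the tests as fitted and are not exact sizes of the change.

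Before the data were examined, 24 gene lists with 329 names in all were fixed. They cover naive pluripotency, general pluripotency, extraembryonic endoderm transcription factors, primitive endoderm surface and endocytic markers, parietal endoderm, visceral endoderm, basement membrane, trophoblast, mesendoderm and definitive endoderm, neuroectoderm, mesoderm and endothelium, and fibroblasts. They also cover the retinoic acid pathway, FGF and ERK signalling, Nodal and activin signalling, epithelial junctions, the lysosome, ER protein folding and secretion, DNA methylation and Polycomb, imprinted genes, proliferation, D cyclins and CDK inhibitors, germline genes, and sex-linked genes. Some genes are members of several lists, so the lists are not independent of each other. Sparc, Nid2, Col4a1 and Lama1 are in both parietal endoderm and basement membrane. Tdgf1 and Gdf3 are in both general pluripotency and Nodal and activin signalling, and Fst is in the latter and in parietal endoderm. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. GO terms given in the deposited annotation, with 10 to 300 tested genes, were tested with a one-sided hypergeometric test on called genes at least 2-fold changed. The genes named were also set by a rule fixed at that time: 12 lineage markers, the 10 largest changes in each direction among called genes whose groups did not overlap, up to 4 members of each list (the 2 largest and the 2 smallest changes), and the 3 leading genes of a GO term. Names of clones and predicted genes were left out of the largest changes. Not every gene that the rule selects is named, and some of their values are not reported here.

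cXEN and mESC samples carry the numbers 1 to 3. Deviations from the group means of same-numbered samples correlated across genes at 0.313, 0.149 and 0.219, so the samples were treated as paired in an alternative fit. This pairing comes from the data and is not stated in the labels.

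The fit was tested on simulated data with 200 changed probes. In the cXEN and eXEN setting it recovered 8% of changes of 2-fold, 50% of 4-fold and 82% of 8-fold, with 0 false calls. In the cXEN and mESC setting these shares were 14%, 72% and 86%, with 3 false calls, and in the eXEN and mESC setting 10%, 64% and 82%, with 2. The planted list was called in each setting and 0 of 23 random lists were. The simulation kept more probes than the real data, for example 26195 against 17654 in the cXEN and eXEN setting, so these shares are a rough guide.

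Alternatives covered background correction, normalization, the authors' own values, probe filters, averaging of probes, the samples in the fit, the variance model, array weights, the replicate block, a test against 2-fold, and leaving out each array. The default estimator of array weights stopped before it converged. A gene-by-gene estimator was therefore added after the data had been seen, together with a fit that holds the arrays with higher background as a block and a selection of genes on cXEN minus mESC. Second tested probes were compared for all lineage markers, largest changes and list members, also after the data had been seen. Among those called with a second tested probe, it showed under 0.25 of the change for 6 of 73 in cXEN minus mESC, 6 of 69 in eXEN minus mESC and 4 of 9 in cXEN minus eXEN. A block for slides was not run, since the files used here give no slides.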

Results

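The series compares gene expression in converted XEN cells with that in mouse embryonic stem cells and in embryo-derived XEN cells. XEN cells are cultured counterparts of the extraembryonic endoderm. The 8 arrays comprise 3 mESC, 3 cXEN and 2 eXEN samples, with 13935 to 15408 probes detected on each. Log2 values are normalized intensities, errors are SE unless named, and counts are of genes.

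The arrays of both XEN groups resembled each other more than either resembled mESC. The mean correlation between cXEN and eXEN arrays was 0.944 (range 0.932 to 0.952), close to the 0.951 (0.941 to 0.959) among cXEN arrays. It was 0.808 between cXEN and mESC and 0.802 between eXEN and mESC. The correlation was 0.968 for the eXEN pair and 0.965 to 0.986 among mESC. These correlations run across probes, which are not independent replicates, and the first principal component held 70.9% of the variance. The second held 9.47% and parted the XEN groups, with cXEN arrays at 0.21 to 55.7 and eXEN arrays at -35.7 and -41.8. That parting was not tested.

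The first comparison asked how converted cells differ from their starting cell type. Transcription factors of the extraembryonic endoderm were much higher in cXEN: Sox17 was at least 77.4-fold higher, with a fitted log2 fold change of 6.55 ± 0.20 (adjusted p = 9.57e-08). Sox7 rose by 6.23 ± 0.27 and Gata6, a regulator of primitive endoderm, by 5.59 ± 0.24. Foxa2 was at least 9.41-fold and Gata4 at least 8.57-fold higher. The pluripotency factors Nanog, at least 96.3-fold lower, and Sox2, at least 15.6-fold lower, fell below detection on every cXEN array, and Pou5f1 changed by -6.05 ± 0.59 (adjusted p = 5.13e-05). The second probe of Sox2, with a mean of 4.78 and 0 detections in cXEN, had a fitted change of -0.64 against -4.86 on the probe used. In all, 2478 genes were higher and 2873 lower of the 12603 tested, of which 1698 and 1939 changed at least 2-fold.

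Pou5f1, probed at 35643356 to 35643405 on chromosome 17, stood at 7.59 on cXEN1 and at 5.17 and 5.06 on the other cXEN arrays, against a mean of 11.99 ± 0.31 (SD) in mESC. Nanog, probed at 122664570 to 122664619 on chromosome 6, averaged 4.38 ± 0.13 (SD) in cXEN and 11.79 ± 0.30 (SD) in mESC. Gata6, probed at 11085485 to 11085534 on chromosome 18, averaged 12.55 ± 0.10 (SD) and 6.96 ± 0.26 (SD). Among the other markers fixed in advance, the growth factor receptor Pdgfra was higher by 4.62 ± 0.27 and the endocytic adaptor Dab2 by 4.62 ± 0.33. The trophoblast factor Cdx2 was detected on 1 array and the visceral endoderm product Afp on 0, so neither was tested.

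**Figure D1:**
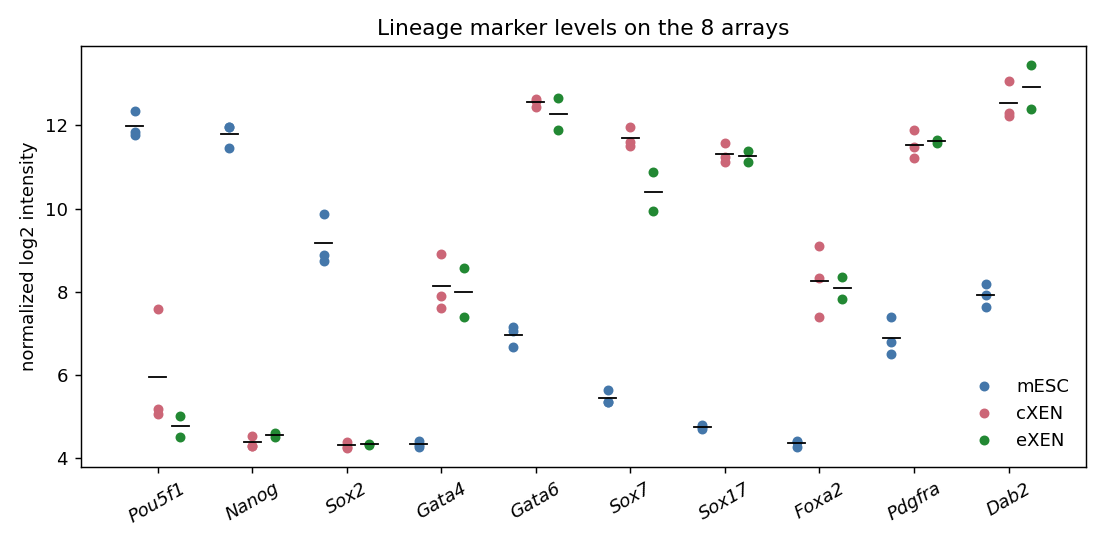
Normalized log2 intensity (vertical axis) of 10 lineage markers (horizontal axis) on each array, with points for arrays coloured by group and a black line for each group mean. Pou5f1, Nanog and Sox2 are low in both XEN groups, with Pou5f1 at 7.59 on cXEN1, and the other markers are lower in mESC than in XEN. Of these, Dab2, Gata6, Pdgfra and Sox7 were still detected on all 3 mESC arrays, with means of 7.91, 6.96, 6.90 and 5.45.

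The largest increases beyond these were in Myl3, a myosin light chain (at least 227-fold), Hs3st1, a heparan sulfate sulfotransferase (7.80 ± 0.32), Fxyd3 (at least 77.5-fold), Drp2 (6.52 ± 0.39), Hkdc1 (at least 59.4-fold), Pth1r, the parathyroid hormone receptor (at least 57.5-fold), Tinagl1 (6.05 ± 0.54) and Slco2a1, a prostaglandin transporter (at least 47.2-fold). The largest decreases included Esrrb, a nuclear receptor of naive pluripotency (at least 184-fold), Spp1 (at least 87.0-fold), Ooep (-7.31 ± 0.35), Dppa4 (-7.28 ± 0.40), Fxyd6 (-7.20 ± 0.38), Mgp (at least 96.7-fold), Zfp42 (-6.81 ± 0.41) and Wfdc2 (at least 55.3-fold). Dppa5a changed by -6.95 ± 1.78 (adjusted p = 0.0123). It stood at 12.95 on cXEN1, near the 14.40 to 14.67 of mESC, and at 5.21 and 4.61 on the other cXEN arrays.

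Some gene lists of extraembryonic endoderm and of secretion were higher in cXEN by camera, while the lists of visceral endoderm and of mesendoderm and definitive endoderm were not called by camera (adjusted p = 0.876 and 0.332) but were lower by fry (adjusted p = 0.0360 and 0.00234). Few mesendoderm genes were tested, and the visceral endoderm genes went both ways. Of 12 extraembryonic endoderm factors tested, 9 were higher and 1, Hhex, was lower (camera adjusted p = 7.61e-07). Hhex changed by -0.69 ± 0.23, a call that ended with the replicate block (adjusted p = 0.0532) and without any of 6 arrays, for example without mESC3 (-0.57, adjusted p = 0.149). Of 14 parietal endoderm genes 12 were higher (1.33e-09), led by Pth1r and Fst, a follistatin (5.91 ± 0.32). Krt19, at 1.11 ± 0.78, was not called, but was with the replicate block (adjusted p = 0.0480) and without cXEN2 (2.07, adjusted p = 0.0122). Of 17 basement membrane genes 14 were higher (4.53e-08), among them Lama1, a laminin chain (5.54 ± 0.20), and Col4a2, a type IV collagen chain (5.23 ± 1.43), whose call ended without mESC3 (5.10, adjusted p = 0.0534). Of 14 genes of protein folding and secretion 11 were higher (1.82e-05), with Pdia6 at 2.29 ± 0.26 and P4hb at 2.08 ± 0.18, both disulfide isomerases. These calls held with an estimated correlation, at adjusted p = 0.0213 for the first 3 lists and adjusted p = 0.0397 for protein folding.

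Among primitive endoderm surface and endocytic markers, 7 of 11 were higher and Bmp4, a signalling ligand, was lower at -4.78 ± 0.25 (camera adjusted p = 0.00700). Among lysosomal genes 9 of 16 were higher, including Ctsh (4.49 ± 0.30) and Lgmn (2.50 ± 0.49), both lysosomal proteases, and Hexa, a hexosaminidase, was lower at -3.06 ± 0.48 (0.00219). With an estimated correlation both lists had adjusted p = 0.233.

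Pluripotency lists moved down. Of 13 naive pluripotency genes 11 were lower (camera adjusted p = 7.61e-07), and 1, Klf4, was higher at 0.96 ± 0.31. That call ended without mESC2 (0.79, adjusted p = 0.118), mESC3 (0.93, adjusted p = 0.0986) or cXEN1 (0.61, adjusted p = 0.0843). Of 14 general pluripotency genes 12 were lower and 0 higher (6.47e-07), with Lin28a at 0.51 ± 0.24 and Sall4 at 0.38 ± 0.21 not called. With an estimated correlation both lists had adjusted p = 0.0254. Of 5 germline genes all 5 were lower (camera adjusted p = 0.000360), including Dazl, an RNA-binding protein of germ cells (at least 14.0-fold). Of 12 Nodal and activin genes 8 were lower and 2 were higher (0.00388), with Nodal at least 22.5-fold lower. Of 9 genes of DNA methylation and Polycomb 4 were lower (0.00549), including Dnmt3l (-4.91 ± 0.70) and Cbx7 (-3.77 ± 0.27). With an estimated correlation these 3 lists had adjusted p = 0.0650.

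Fibroblast genes moved with the pluripotency lists: 8 of 10 were lower in cXEN (camera adjusted p = 0.000154), with Dcn at least 16.5-fold and Col6a3 at least 14.3-fold lower. With an estimated correlation the list had adjusted p = 0.0650. This list was fixed as one of feeder cells, and whether RNA of such cells was present in the mESC samples was not tested. Adjusted over the list alone, 13 protein folding genes were higher, and 1 basement membrane, 9 fibroblast, 9 Nodal and 6 DNA methylation genes were lower. For the other 7 lists called here, the counts adjusted over the list alone were the same as above.

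Of 632 GO terms, 16 were enriched among higher and 12 among lower genes. Cell adhesion held 51 higher genes against 24.1 expected (adjusted p = 3.69e-05) and basement membrane 15 against 4.32 (adjusted p = 0.00129). Sulfotransferase activity held 6 of its 10 genes (adjusted p = 0.0466), led by Hs3st1 and Chst15. Among lower genes, growth factor activity held 30 against 10.4 (adjusted p = 5.14e-06), led by Gdf3, Nodal and Bmp4. The proteinaceous extracellular matrix was enriched in both directions, with 34 higher and 40 lower genes of 114. Without the fold threshold, 8 of the 16 and 4 of the 12 terms of cXEN minus mESC were kept. Of those named, sulfotransferase activity (adjusted p = 0.0982) and matrix among higher genes (adjusted p = 0.0553) were lost.

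The second comparison set the positive control against the negative control. In eXEN, Sox17 was at least 74.6-fold higher (fitted 6.50 ± 0.22, adjusted p = 2.48e-07), Gata6 rose by 5.31 ± 0.27 and Sox7 by 4.95 ± 0.30. Foxa2 was at least 8.35-fold and Gata4 at least 7.77-fold higher, Pdgfra rose by 4.71 ± 0.31 and Dab2 by 5.01 ± 0.37. Pou5f1 was at least 120-fold, Nanog at least 105-fold and Sox2 at least 17.1-fold lower, with the second Sox2 probe at -0.63 and not called (adjusted p = 0.0507). Of the tested genes 2302 were higher and 2655 lower, with 1721 and 1964 changed at least 2-fold.

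The largest increases included Adamts9, a secreted protease (at least 143-fold, with its second probe fitted at 3.52), Hs3st1 (7.54 ± 0.36), Fst (7.18 ± 0.36), Ttr, the carrier of thyroid hormone (at least 90.4-fold), Slco2a1 (at least 86.5-fold), Foxq1 (6.46 ± 0.59), St3gal6 (6.36 ± 0.41), Hkdc1 (at least 61.3-fold) and Nxf7 (at least 53.04-fold). The largest decreases included Dppa5a (-9.28 ± 1.99), Esrrb (at least 201-fold), Fxyd6 (at least 161-fold), Ooep (at least 128-fold), Mgp (at least 106-fold), Spp1 (at least 95.1-fold), Dppa4 (-7.21 ± 0.45) and Rps4l, a ribosomal protein gene (at least 92.8-fold).

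The same 12 lists were called by camera, 6 in each direction. Higher were 10 of 12 extraembryonic endoderm factors (adjusted p = 3.39e-07), all 14 parietal endoderm genes (4.42e-10) and 13 of 17 basement membrane genes (4.64e-09), each with adjusted p = 0.0188 with an estimated correlation. Of 14 protein folding genes 11 were higher (7.99e-05, but adjusted p = 0.0527 with an estimated correlation). Of 11 primitive endoderm markers 7 were higher and 1 lower (0.00990), and of 16 lysosomal genes 10 were higher and 1 lower (0.00366), but both had adjusted p = 0.249 with an estimated correlation. Lower were 9 of 13 naive and 12 of 14 general pluripotency genes (both 3.39e-07, and adjusted p = 0.0247 with an estimated correlation), with Lin28a higher at 1.26 ± 0.27. Also lower were 7 of 10 fibroblast genes (0.000201), 6 of 9 genes of DNA methylation and Polycomb (0.00475) and all 5 germline genes (0.000323), but these had adjusted p = 0.0706 with an estimated correlation. Of 12 Nodal and activin genes 6 were lower and 2 higher (0.0215), but with adjusted p = 0.104 with an estimated correlation. For eXEN minus mESC, the replicate block also ended the call of that list (adjusted p = 0.0522).

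Adjusted over the list alone, 14 basement membrane, 11 lysosomal and 3 Nodal and activin genes were higher and 8 fibroblast genes lower, and the other counts were those above. Col4a2 was at 13.71 on eXEN1 and 6.25 on eXEN2, and its change of 1.29 ± 1.60 was not called. It was -2.44 without eXEN1 (adjusted p = 0.00173) and 5.03 without eXEN2 (adjusted p = 6.72e-05).

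Enriched GO terms numbered 16 among higher and 10 among lower genes. Lipid metabolism held 33 higher genes against 17.4 expected (adjusted p = 0.0111), with Vldlr, a lipoprotein receptor, and Insig1, a regulator of sterol synthesis, among its leading genes. Receptor-mediated endocytosis held 6 of its 10 genes (adjusted p = 0.0448), led by Dab2, Cubn and Lrp2. Without the fold threshold, 4 of the 16 and 5 of the 10 terms were kept, lipid metabolism among them (adjusted p = 0.0357), and receptor-mediated endocytosis was lost (adjusted p = 0.122).

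Fold changes of both XEN groups against mESC correlated across genes at 0.913, with a covariance of 1.60. Both comparisons use the same mESC arrays. Arrays simulated without any change, with 3 simulated mESC arrays shared by both comparisons, gave 0.448 and a covariance of 0.0439. The covariance exceeded the simulated one by 1.56. Of the genes called higher, 1753 were shared against 453 for independent lists, and of those called lower, 2221 against 605. The arrays simulated without change shared on average 0.01 higher and 0 lower genes. Almost no gene is called where none changes, so these counts cannot measure what shared arrays add to the overlap. The 3 mESC arrays cannot be split into groups of 2, so part of the excess overlap over independent lists may come from the shared arrays. Another 12 genes were called in opposite directions.

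**Figure D2:**
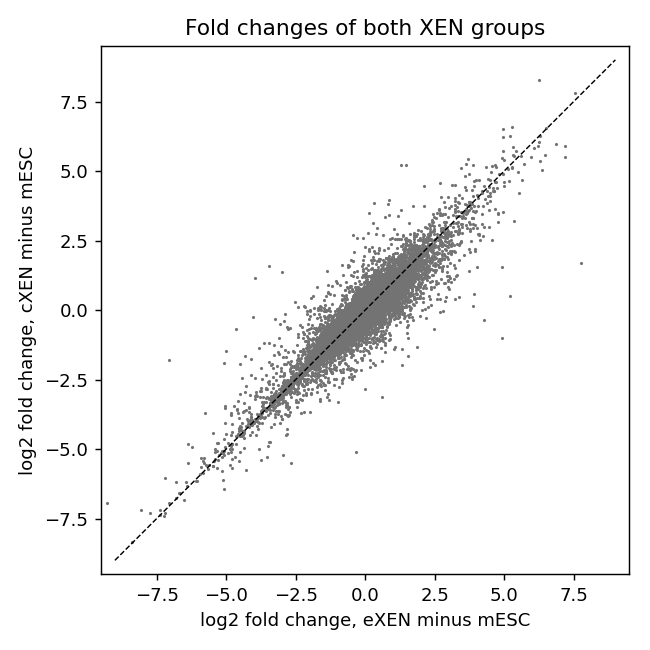
Log2 fold change against mESC in cXEN (vertical axis) and in eXEN (horizontal axis), with 1 point per gene and a dashed line of equality. The values correlate at 0.913, and both share the mESC arrays.

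The third comparison set converted against embryo-derived XEN cells. Rps4l was at least 27.0-fold (adjusted p = 6.79e-06), Abhd16a at least 24.8-fold and Lxn, a carboxypeptidase inhibitor, at least 20.7-fold higher in cXEN, each by its only tested probe. The main probe of Adamts9 was lower in cXEN, at -6.08 ± 0.21 (adjusted p = 2.37e-06), but its second probe was flat at -0.08, with fitted values against mESC, where it was detected on 0 arrays, of 3.44 in cXEN and 3.52 in eXEN. Grb10, an imprinted adaptor of growth signalling, was at least 16.4-fold lower by its main probe (fitted -4.80), while its second probe, detected on 0 cXEN arrays, was fitted at -1.17 and not called. The lineage markers fixed in advance did not pass the test: Sox17 differed by 0.05 (95% interval -0.44 to 0.54), Gata6 by 0.28 (-0.33 to 0.89) and Gata4 by 0.14 (-0.81 to 1.09). Sox7 differed by 1.29 ± 0.30 (0.61 to 1.96), with an adjusted p of 0.0954. A total of 64 genes were higher and 69 lower, all at least 2-fold, and 1660 had an unadjusted p below 0.05.

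Also higher were Kcnk6 (at least 12.6-fold), Spsb4 (at least 6.27-fold), Ptprb (at least 5.20-fold), Mgll (3.01 ± 0.29), Ddx3y, a Y-linked helicase (2.93 ± 0.53), Sh3d21 (at least 6.48-fold) and Slc35g2 (at least 3.59-fold). Also lower were Tomm22, a mitochondrial import receptor (-4.63 ± 0.22, but 0.15 on its second probe), Uap1 (-3.38 ± 0.31), Diras2 (-3.34 ± 0.30), Homer2 (at least 6.72-fold), Nudt7 (at least 6.15-fold, but -0.52 on its second probe), Dtd2 (-2.83 ± 0.50) and Tmem141 (at least 3.79-fold). Of the fixed lists 0 were called by camera, 0 with an estimated correlation and 0 by fry, and the lowest camera adjusted p was 0.0664, for sex-linked genes. Single list members called were Ctsl, a lysosomal protease (2.01), the imprinted gene Impact (1.40) and the cell cycle inhibitor Cdkn2b (at least 4.42-fold lower), besides Grb10 and Ddx3y. Adjusted over the list alone, 2 parietal endoderm genes were higher and 1 lower, 2 epithelial junction genes higher and 1 lower, and 2 lysosomal genes higher. The counts were 1 and 0 for extraembryonic endoderm factors and for sex-linked genes, 1 and 1 for imprinted genes and for D cyclins, 0 and 2 for Nodal, and 0 and 1 for basement membrane and for trophoblast, and 0 for the other lists. Of the GO terms 0 were enriched in either direction by the hypergeometric test, with 4 and 7 terms at an unadjusted p below 0.05.

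The counts of cXEN minus eXEN were 10 higher and 12 lower with only these groups in the fit, and they moved with single arrays. They were 175 higher and 193 lower without cXEN2, 21 and 31 without eXEN1 and again without eXEN2, 26 and 27 without mESC3, while 41 genes were higher without mESC2 and 43 and 41 lower without mESC2 and mESC1. Calls ended without eXEN1 for Grb10 (-3.92, adjusted p = 0.113), and without either eXEN array for Ctsl (0.0872 and 0.0867), Impact (0.0934 and 0.0909), Sh3d21 (0.107 and 0.106) and Slc35g2 (0.107 and 0.0932). Those of Ddx3y and Dtd2 ended without any of the mESC arrays and without others, with an adjusted p of up to 0.220 when an eXEN array was left out. With the authors' values the calls of Grb10 (-2.73, adjusted p = 0.135), Sh3d21 (1.34, 0.0752), Slc35g2 (1.13, 0.0807) and Ddx3y (2.06, 0.0969) ended, and with the replicate block those of Grb10 (0.0635), Sh3d21 (0.0651), Ctsl (0.0504), Ddx3y (0.106) and Dtd2 (0.0784).

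A further count asked how far cXEN reached the eXEN level. Of 3685 genes changed at least 2-fold in eXEN, 3599 were not called between cXEN and eXEN, which does not show that they were equal. Another 75 were called with cXEN on the mESC side and 11 with cXEN beyond eXEN, such as Myl3 (2.05, adjusted p = 0.00636, or 1.70 and 0.0531 without eXEN2). The median gene stood at 92.5% of the way from mESC to eXEN, where genes selected on cXEN minus mESC instead had eXEN at 97.2% of the way to cXEN. Of the 75 genes, 33 had cXEN past the mESC level, away from eXEN, and 42 had it between mESC and eXEN. The count with cXEN on the mESC side was 210 without cXEN2, 36 without eXEN1 and again without eXEN2, and 33 without mESC3.

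Within the XEN arrays, 9 of 100 combinations of array and chromosome had a median deviation from the other XEN arrays of at least 0.25. The largest were 0.42 on chromosome 18, 0.38 on chromosome 16 and -0.36 on chromosome 14 in eXEN2, 0.39 on chromosome 1 in eXEN1, and -0.34 on chromosome 16 in cXEN2.

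**Figure D3:**
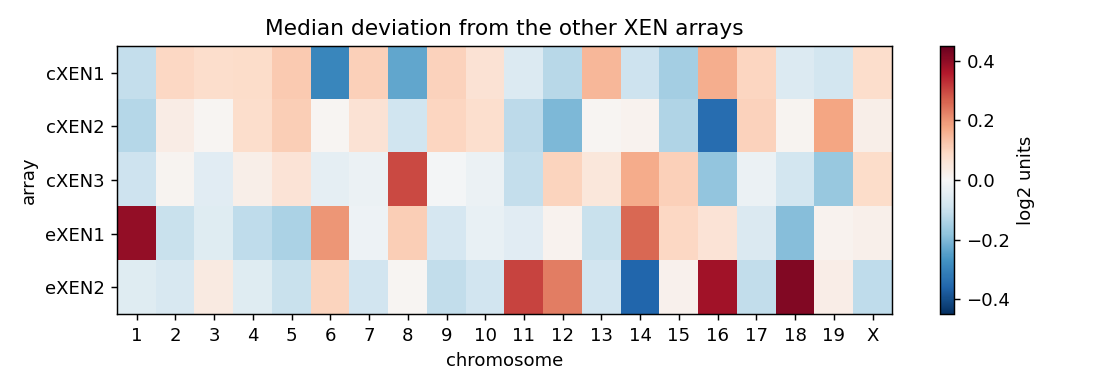
Median log2 deviation (colour) of the genes of each chromosome (horizontal axis) on each XEN array (vertical axis) from the mean of the other XEN arrays. The largest value is 0.42, on chromosome 18 in eXEN2.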

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

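Both tests on Pou5f1 were chosen after its values had been seen. The test with high-background arrays as a term was added after the array backgrounds had been seen, and the outcomes that would count for or against the other explanations were written before those tests were run. A set of 12 genes was called in opposite directions in cXEN and eXEN against mESC, and the difference itself was tested with limma. The same arrays selected these genes, so the outcome of that test was largely fixed and adds no support. Groups of 3 arrays or fewer were not searched for outlying samples. Values are fitted log2 fold changes, cXEN minus eXEN, and are not exact sizes where a group was not detected. With 0 eXEN arrays detected, only the bounds are known for Abhd16a (at least 24.8-fold), Lxn (20.7), Kcnk6 (12.6), Sh3d21 (6.48), C330024D21Rik (3.43), Tmem106b (2.71) and Zfp871 (2.51), and with 0 cXEN arrays detected for Homer2 (6.72) and Nudt7 (6.15). cXEN was above eXEN for Lxn (5.11), Abhd16a (5.06), Kcnk6 (4.38), Sh3d21 (2.78), Osbp (2.44), C330024D21Rik (2.21), Tmem106b (2.06), Zfp871 (1.80) and A930005H10Rik (1.47). cXEN was below eXEN for Homer2 (-3.31), Nudt7 (-3.22) and C030002B11Rik (-2.41). The calls of some of these genes against mESC depended on single arrays. Against mESC, Kcnk6 in cXEN lost its call without mESC2 (1.09), cXEN1 (1.06) or cXEN3 (1.26). In eXEN, Homer2 lost its call without eXEN1 (1.10), Nudt7 without eXEN2 (1.04), and Sh3d21 without mESC2, mESC3, eXEN1 or eXEN2.

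The 133 genes that differ between cXEN and eXEN could come from several sources. A strain variant under a single probe would leave second probes flat, yet over the 35 genes with a second tested probe the median was 1.20 in the direction of the first probe (1.88), and 34 went the same way. For 6 of them, Adamts9, Tomm22, Nudt7, Grb10, Slu7 and Hmgn2, the second probe showed under 0.25 of the change. That of Adamts9 (mean 6.62) was detected on 3 cXEN and 2 eXEN arrays and flat, so a difference tied to 1 probe may account for it. The other second probes were dim (means 4.84 to 5.40), which limits the change they can show. Those of Grb10 and Nudt7 were detected on 2 eXEN and 0 cXEN arrays, in the direction of their main probes. That of Tomm22 was detected on 3 cXEN and 1 eXEN arrays, and its fitted change of 0.15 went against the main probe (-4.63). Dimness alone therefore does not account for Tomm22. A difference tied to 1 probe stays open for genes with such dim second probes and for genes with 1 tested probe. With the 2 high-background arrays as a term 100 genes were still called. These arrays, cXEN3 and eXEN2, lie 1 in each group, so the term could take little from the group difference. Array background therefore stays open. Of the 109 genes with a known chromosome, 0.917% lay on Y. Chromosome Y holds too few genes to make up most of the 133, so this share could not have been large. Signal remaining from the mESC state stays open: cXEN lay on the mESC side of eXEN for 77.4% of the genes (exact interval 69.4 to 84.2), but this counts genes with cXEN past mESC, and for only 73 of 133 was cXEN nearer to mESC than eXEN was. The same 2 eXEN arrays enter the selection and the side, so most genes could fall on the mESC side without such signal. The interval also treats genes as independent. Differences between cell lines, with 2 eXEN lines, were not tested.

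Pou5f1 stood at least 2.47 log2 units above the mean of the 4 other XEN arrays on cXEN1, of which 0 detected it. A faulty probe is argued against by the second Pou5f1 probe, which was at least 2.18 higher there (fitted 2.77, SD of the other arrays 0.18). Carry-over of mESC in the whole would raise abundant mESC genes by a like share. Pou5f1 had 3.95% of its mESC signal, while the median of 100 abundant mESC genes was 0.262% (bootstrap interval 0.101 to 0.562). The 100 leave out genes detected on any eXEN array. Dppa5a, detected on 1 of them, was left out, although on cXEN1 it stood far above the other cXEN arrays. However, 22 of the 100 genes had a share at least that of Pou5f1. Some of these do not point to remnants in cXEN1. Rps4l was 9.82 there against a mean of 9.83 in cXEN and 4.57 in eXEN, so its share reflects the eXEN arrays. Gusb stood above its mESC mean (9.92 against 8.72). Incomplete silencing of others among the mESC genes in this culture may remain. That is a hypothesis found and tested on the same data.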

How the results depend on the processing

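Alternatives not planned, namely the block of high-background arrays, the gene-by-gene array weights and the mirrored selection, were chosen after seeing the data. Counts are given as higher and lower. For cXEN minus eXEN (64 and 69), they were 38 and 37 without a probe filter, 22 and 19 with probes detected on all 8 arrays, 10 and 12 with only the 2 groups compared, 38 and 38 with the replicate block and 9 and 9 against 2-fold. Higher genes were 42 with an offset of 50 and 37 with the authors' table or the series matrix values. Leaving out 1 array gave 21 to 175 and 27 to 193. Genes with cXEN on the mESC side of eXEN (75) were 46 with the authors' table or the series matrix values, 45 without a filter, 24 with all 8 arrays detected, 49 with the replicate block, 11 against 2-fold and 33 to 210 without 1 array. The causes of these moves were not tested, although the all-array filter tests fewer genes.

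Tested against 2-fold, counts were 559 and 809 in cXEN minus mESC and 531 and 749 in eXEN minus mESC. With probes detected on all 8 arrays, lower genes were 1375 in cXEN, and eXEN counts were 1510 and 1263. The correlation of fold changes was 0.887 with all arrays detected and 0.893 to 0.915 without 1 array. With an estimated correlation, lists lower in cXEN were 2, and lists in eXEN were 3 higher and 2 lower, while fry gave 10 lower in cXEN, including visceral endoderm, mesendoderm, epithelial junctions and imprinted genes. In cXEN minus eXEN, 1 list was higher with median centring, and 0 to 1 without 1 array. Without a fold threshold, 4 GO terms were enriched among lower genes in cXEN, and 5 and 6 among higher and lower genes in eXEN.

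The mean correlations of arrays were 0.952 (cXEN and eXEN), 0.839 (cXEN and mESC) and 0.833 (eXEN and mESC) without background correction. With the authors' table they were 0.954, 0.849 and 0.842, and 0.961 among cXEN. Without a filter they were 0.969, 0.902 and 0.900, with 0.972 among cXEN and 0.981 for the eXEN pair.

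In cXEN minus mESC, the replicate block gave 2699 and 3044 genes. Among named genes it ended the call of Hhex and added calls for Calr, Cdkn1b, Cldn6, Dsp, Dusp4, Eif2s3y, Gata3, Krt19, Otx1, Pdgfrb and Suz12, and it changed no other call of that comparison. For eXEN, samples share only a number: deviations correlated at 0.190 and 0.126 with mESC and at 0.167 and 0.0790 with cXEN. Of the 8 arrays, 7 correlated best with an array of their own number, and eXEN2 did not. The block still held eXEN2 as number 2, which its values do not bear out. Block results of both comparisons with eXEN rest on that number. The block gave 2404 and 2724 genes in eXEN minus mESC. Where 1 eXEN array was left, it was assumed to vary like the other groups.

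Of called values of named genes, leaving out 1 array kept 991 of 1040 in cXEN minus mESC, 960 of 1048 in eXEN minus mESC and 168 of 192 in cXEN minus eXEN. Other settings kept 2019 of 2116, 2001 of 2129 and 341 of 388. These settings are not independent, since the authors' table and the series matrix hold the same values. Genes that a probe filter removed were not counted as lost. The named genes also include the largest called changes of these data, which favours kept calls. Col4a2 in eXEN minus mESC, not called at 1.29, reversed to -2.44 without eXEN replicate 1 and was 5.03 without eXEN replicate 2. Array weights by the default estimator stopped before converging, with 8.86 for mESC3, against 4.64 by the gene-by-gene estimator. Dim probes are limited by signal over background, the lowest detected value of an array being as high as 5.27.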

Other observations

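The gene lists were fixed before the data were seen. The mirrored selection and the wider assignment of chromosomes were chosen after seeing the data, the latter after a first run of the test. The lists below were not called by camera, and unless fry is named, adjusted p-values and directions of a list are those of camera. By fry, a test of each list on its own rather than against other genes, 5 of them were called in cXEN: retinoic acid up (adjusted p = 0.00141), and mesendoderm (0.00234), epithelial junctions (0.00267), imprinted genes (0.0329) and visceral endoderm (0.0360) down. In eXEN fry called 4 of them, retinoic acid up (0.000256), and mesendoderm (0.00407), epithelial junctions (0.00367) and sex-linked genes (0.0145) down. Among visceral endoderm genes, 4 of 13 were higher and 5 lower in cXEN (adjusted p = 0.876) and 5 and 3 in eXEN (0.900). Ttr was at least 28.5-fold higher in cXEN, and Otx2, a factor of the anterior visceral endoderm and epiblast, at least 20.8-fold lower. Their median in cXEN was 0.27, also with bounds, while the mean was -0.16 and camera pointed down. Of 7 trophoblast genes, 3 were higher and 2 lower in cXEN (0.681), with Tfap2c at least 40.7-fold lower, and 5 and 2 in eXEN (0.311). Their median in cXEN was 1.04, or 0.34 with bounds, and the mean -0.15, and camera pointed up while fry pointed down. Of 9 retinoic acid genes, 3 were higher and 4 lower in each XEN group (0.869 and 0.695). Stra6, a retinol transporter, was at least 21.2-fold higher in cXEN, and Cyp26a1, which degrades retinoic acid, rose by 3.44 ± 0.52, but its second probe was at 0.75 and not called. The list's median in cXEN was -0.49 and its mean 0.63, in eXEN -0.30 (-0.04 with bounds) and 0.83, and camera pointed up in both.

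Of 12 FGF and ERK genes, 3 were higher and 6 lower in cXEN (adjusted p = 0.532) and 2 and 6 in eXEN (0.370). Of 11 epithelial junction genes, 1 was higher and 6 lower in cXEN (0.227) and 3 and 6 in eXEN (0.172), with Cldn4, a tight junction protein, at least 23.1-fold lower in cXEN. Of 13 imprinted genes, 2 were higher and 7 lower in cXEN (0.140) and 1 and 4 in eXEN (0.164). Of 15 proliferation genes, 0 were higher and 3 lower in each group (0.197 and 0.178). Of 9 D cyclins and CDK inhibitors, 1 was higher and 2 lower in cXEN (0.876) and 3 and 1 in eXEN (0.850). Ccnd1 changed by -6.17 ± 0.31 in cXEN and Ccnd2 by 2.99 ± 0.57. Their median in cXEN was 0.25 and the mean -0.41, in eXEN -0.30 and -0.12. Camera pointed up in both groups and fry down (fry adjusted p = 0.0690 and 0.566). Few mesendoderm (3), neuroectoderm (4) and mesoderm and endothelium (4) genes were tested. In cXEN 0, 0 and 2 of these were higher and 2, 1 and 1 lower (0.332, 0.876 and 0.824), and in eXEN 1, 0 and 1 were higher and 1, 1 and 1 lower (0.349, 0.779 and 0.893). Of 5 sex-linked genes, 1 was lower in cXEN (0.750) and 3 in eXEN (0.0874). Adjusted over the list alone, the counts for cXEN became 4 and 2 for trophoblast, 1 and 2 for mesendoderm, 1 and 1 for neuroectoderm, 4 and 6 for FGF and ERK, and 2 and 6 for epithelial junctions. For eXEN they became 5 and 4 for visceral endoderm, 1 and 2 for mesendoderm, 4 and 4 for retinoic acid, 1 and 5 for imprinted genes, and 0 and 2 for proliferation. The remaining counts stayed the same.

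The next genes were picked for their spread over the arrays, after seeing the values, and that spread was not tested. Of the imprinted genes, Grb10 stood at 4.31 to 4.65 on the cXEN arrays and at 8.36 to 10.99 on all others. H19 stood at 5.60 on cXEN2 and at 9.25 or more on the other arrays. Igf2 stood at 8.81 on cXEN1, 6.29 on cXEN2 and 4.87 on cXEN3. Eif2s3y, on chromosome Y, stood at 8.61 on cXEN3, 5.58 on cXEN1 and 4.37 on cXEN2.

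The count of genes changed between cXEN and mESC was 5351, and the highest among the other splits of the 6 arrays was 0. Every other split mixes mESC and cXEN arrays in both groups, which adds their difference to the spread. A count of 0 was therefore foreseeable and does not bear on the real split. Only 10 splits exist, 1 of which gave as many, so they are too few for a share under 0.05. Of the splits, 4 part as many pairs, and the highest of the other 3 of them was 0.

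The 75 genes with cXEN on the mESC side could be a product of selecting genes on the eXEN arrays. When genes were selected on cXEN minus mESC instead, 58 of 3637 had eXEN on the mESC side of cXEN. The 75 do not exceed this by 1.5 times, so the selection may account for the pattern.

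Shifts over whole chromosomes in single XEN arrays are consistent with differences in gene dosage between the lines, as a hypothesis. The bounds fixed for such a shift were met by 9 of 100 combinations over 5471 genes, where shuffling genes gave a largest shift with a 95th percentile of 0.13. The count was also 9, though not all the same, with the chromosome column of the file alone, which covered 74.3% of genes rather than 85.9%. A shift on 1 array also moves the reference of the others, and no DNA was measured.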
